A study of Mus musculus with 5 samples.

How the data were processed

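The study deposited single-cell RNA sequencing of tdTomato-positive cells sorted from mouse femur marrow, after the distal growth plates and the proximal ends of the bones had been taken off. The mice carried Lepr-cre and a Cre-dependent tdTomato reporter, and about 30000 cells per library were loaded on a BD Rhapsody instrument. There were 5 libraries, 1 per group: control, naive, exhausted, aged and aged-injury. The series text speaks of 4 groups and lists 5. The labels give no batch, no date and no number of animals, but give the ages at surgery of naive and exhausted, which place them 2 weeks after the last ablation, and place aged-injury 1 week after it.

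The values deposited by the authors were matrices of UMI counts per gene and cell, whole numbers with no normalisation, 1 matrix per library. The submitters' processing notes name Seurat 5.1 and the GRCm39 build. The aligner, the counting tool and the rule that called cells are not given in the sources used here. Each library listed only genes detected in it, from 26484 to 27845 genes, and the libraries were joined by gene symbol as deposited, giving 30099 distinct symbols, with an unlisted symbol counted as 0. The EGFP sequence was listed in 4 libraries and not in aged, so a 0 there may also mean that the reference lacked it. No coordinates were used.

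The matrices held 57968 cells, 11204, 7480, 8603, 9814 and 20867 in the order above, with 95397522, 58895655, 68170277, 62179497 and 224155538 UMIs. Cells with at least 500 genes, at least 1000 UMIs and a mitochondrial share of UMIs under 25% were kept, which left 82.6%, 70.1%, 73.0%, 77.0% and 93.4%. Doublets were called per library with scrublet, run through scanpy. It called 0.670%, 0.210%, 0.175%, 0.0265% and 0% of cells, too few for libraries of this size, so it did not work as a doublet filter and doublets remain. After their removal 47743 cells were used, 9191, 5231, 6266, 7558 and 19497, with medians of 8390, 7476, 7267.5, 6668.5 and 9512 UMIs and 2678, 2509, 2345.5, 2298.5 and 3098 genes per cell.

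Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were scaled and reduced to 30 principal components. All libraries were clustered together, without integration, by the Leiden method at resolution 1.0 on a graph of 15 neighbours weighted by shared neighbours, with seed 0. There were 35 clusters. Marker lists for 20 cell classes had been fixed, but the rules that turn them into names were set after the clusters had been seen. A class needed at least 3 of its markers, and at least the fraction 0.33 of them, each detected in at least 10% of the cells of the cluster and at least 1.5-fold higher than in the other cells, and no other class was to have more markers among the 10 leading genes. This named 29 clusters and left 6 unnamed. An unnamed cluster was put with the stroma when its summed stromal marker expression exceeded that of the other classes and Ptprc, a pan-leukocyte gene, was under 100 CPM. The stroma took in 16 clusters and 38765 cells, 7133, 3709, 2885, 6743 and 18295 per library, with 63572462, 32806456, 23047847, 49557599 and 207991345 UMIs. Of its clusters, 5 were reticular-like.

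With 1 library per group no test between groups exists, so values are given with counting intervals and no p-value. Shares of cells have exact Clopper-Pearson 95% intervals, and a share of 0 is given with the limit that 3 cells of the total allow. Gene expression was the sum of UMIs over the stromal cells of a library in CPM, and the ratio of a pair of libraries has an exact conditional binomial 95% interval for Poisson counts. A gene with 0 counts in the lower library was set to a floor of 3 counts there and its ratio is given as a lower bound. UMIs of cells of 1 library are not independent animals, and the intervals do not cover differences between mice, surgeries or library preparations. They also do not cover the sampling of cells, so they are too narrow for a gene whose UMIs come from few cells.

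Before the data were examined, 6 comparisons, 28 gene lists, the marker lists, 14 single genes and the rule for naming further genes had been set. For each list, members with at least 5 CPM in either library were kept, at least 5 members were needed, and the median log2 ratio was given with an order-statistic 95% interval. Each median was placed among 10000 random lists of the same size matched on expression in 20 bins, and is called outside its random range when it lay beyond the 2.5 or 97.5 percentile. The lymphoid and endothelial lists had too few measured members in every comparison. A percentile describes the pair of libraries only and is no p-value. Further named genes had at least 20 CPM in either library, at least 50 counts in the higher one, an interval that left out a ratio of 1, a ratio of at least 2, and no place in a blood or other non-stromal marker list. Mitochondrial, ribosomal and predicted genes were left out, as were genes whose CPM in the non-stromal cells of the higher library was at least 5 times the stromal value. The 10 with the largest ratio in each direction were taken, with up to 4 members of the highest mean expression from each list outside its random range. A few genes that this rule takes are not reported here. Correlations across genes used genes with at least 10 CPM in every library of both ratios. The clock genes, the sex-linked genes and the EGFP counts by class were chosen after the data had been seen.

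The gene ratios and list percentiles were tested on simulated data, in which Poisson counts were drawn for each pair of libraries from their pooled expression at their real stromal UMI totals, with folds planted in a few genes. Counts were drawn independently for each gene, as the intervals assume, so this checks the calculation and not the assumption. Left out were counts clumped in a few cells and list members that vary together because they mark the same cell class. For unchanged genes, the 95% intervals covered the true ratio for 95.2% of 10260 genes in naive against control, 95.0% of 10121 in exhausted against control, 94.9% of 10327 in exhausted against naive, 95.4% of 10026 in aged against control, 95.4% of 10252 in aged-injury against aged and 94.6% of 10312 in aged-injury against naive. For 67 genes planted 2-fold higher, the coverage in the same order was 95.5%, 97.0%, 94.0%, 100.0%, 97.0% and 95.5%. For 67 genes at 1.5-fold it was 92.5%, 95.5%, 97.0%, 97.0%, 91.0% and 98.5%, and for 66 genes at 4-fold 93.9%, 90.9%, 92.4%, 95.5%, 93.9% and 95.5%. Of 300 random lists of 20 genes, 3.33% lay outside the random range in naive against control, 4.00% in aged-injury against aged and 4.33% in each of the other 4 comparisons, and a list planted 2-fold higher lay at percentile 100.0 in all 6.

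Alternatives set in advance were a stricter cell filter, doublets kept, Leiden resolutions of 0.5 and 2.0, TMM scaling, every cell weighted equally, all filtered cells or reticular-like cells alone in place of the stroma, a minimum of 50 CPM, no minimum with 0.5 added to each count, cells thinned to a fixed number of UMIs, and other definitions of a cycling cell. Alternatives added after the data had been seen were named stromal clusters alone, removal of the 5% of cells with the highest doublet score, shares of stromal cells in place of filtered cells, and clusters built without the transgene features. The TMM factors of the stromal sums were 0.9739, 1.0947, 1.0199, 0.9524 and 0.9657. The tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used for the TMM factors alone.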

Results

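Stromal cells that express the leptin receptor gene line the vessels of the bone marrow, hold blood stem cells there with secreted factors, and can give rise to bone and fat cells. The 5 libraries were made from tdTomato-positive cells sorted from femur marrow of mice in which Lepr-cre switches on a tdTomato reporter, and were sequenced as single cells. Marrow ablation is an injury that removes marrow from the bone cavity, where bone then forms before marrow returns. The control library came from uninjured mice of 15 weeks, the naive library from mice of that age ablated at 13 weeks, and the exhausted library from mice of that age ablated at 9 weeks and again at 13 weeks. The aged library came from uninjured mice of 18 months and the aged-injury library from mice of 18 months, 1 week after ablation. There was 1 library per group, with no replicates, so no difference could be set against the spread between animals, and every interval given covers counting error only. The labels give neither a batch nor the number of animals.

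Of the cells kept after filtering, most in 4 of the libraries were stromal, as the sort intended, and the exhausted library was the exception. Stromal cells made up 77.6% of the filtered cells in control, 70.9% in naive, 46.0% in exhausted, 89.2% in aged and 93.8% in aged-injury. Blood cells made up 21.6%, 23.6%, 50.8%, 9.65% and 1.86% in the same order. The tdTomato transcript marked the sorted lineage: it stood at 88.4, 67.4, 66.5, 82.6 and 70.7 CPM (UMI counts scaled to a common library total) in stromal cells against 6.62, 3.45, 3.14, 5.71 and 24.2 CPM in blood cells. A tdTomato molecule was counted in 46.2%, 34.7%, 35.3%, 37.8% and 44.5% of stromal cells. In blood cells, which serve as background here, it was counted in 5.49%, 3.32%, 2.76%, 3.98% and 19.1%. Median molecules (UMIs) per cell were 8302, 7068, 6470, 6534 and 9564 in stromal cells and 8866, 8537, 8026, 7435 and 8956.5 in blood cells. The aged-injury library held the most cells and UMIs, 19497 filtered cells against 5231 to 9191 in the other 4, so its depth and any batch of its own could not be told apart from its group.

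Reticular cells, the CXCL12-rich cells that support blood formation, were the main stromal class in uninjured marrow of both ages, and the ablated libraries held a smaller share of them and a larger share of bone-forming and fat cells. Among stromal cells, reticular-like cells made up 74.6% (95% interval 73.6 to 75.6) in control and 70.2% (69.1 to 71.3) in aged. After ablation they made up 41.4% (39.8 to 43.0) in naive, 57.4% (55.6 to 59.2) in exhausted and 52.5% (51.8 to 53.2) in aged-injury. Osteoblast-lineage cells, which are preosteoblast-like and osteoblast-like cells together, made up 8.20% (7.57 to 8.86) in control, 20.5% (19.3 to 21.9) in naive, 13.9% (12.6 to 15.2) in exhausted, 6.39% (5.82 to 7.002) in aged and 15.2% (14.7 to 15.7) in aged-injury. Most of these were preosteoblast-like, at 7.95%, 20.2%, 12.9%, 6.29% and 12.2%. Mature osteoblast-like cells, led by the osteocalcin genes, were 0.252%, 0.377%, 0.936%, 0.104% and 2.97%, and 89.16% of all cells in their cluster came from the aged-injury library. EGFP, not listed in aged, took part in building this cluster, which held 18, 14, 27, 7 and 543 cells. Without the transgene features the class held 66, 69, 46, 39 and 783 cells. Its shares and the order of naive and exhausted therefore depend on this choice, while aged-injury held the most cells either way. Over all filtered cells, the reticular-like shares were 57.9%, 29.3%, 26.4%, 62.6% and 49.3% and the osteoblast-lineage shares 6.36%, 14.6%, 6.38%, 5.70% and 14.3%. On that scale, where blood cells take their part, the exhausted library stood level with control for bone-forming cells.

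The smaller stromal classes also differed between the libraries. Adipocyte-like cells, marked by the lipid-droplet genes Plin1 and Cidec, were 0.379% of stromal cells in control, 3.83% (3.23 to 4.50) in naive, 2.08% in exhausted, 0.341% in aged and 1.14% in aged-injury. Pericyte and smooth-muscle-like cells, the contractile cells of vessel walls, were 0.308%, 3.13%, 1.94%, 0.445% and 1.88%. Fibroblast-like cells were 2.26%, 0.917%, 2.77%, 1.10% and 2.69%, lowest in naive and aged. Chondrocyte-like cells, the cells of cartilage, were counted almost only in aged-injury, where 225 cells made up 1.23% (1.08 to 1.40). There were 2 such cells in naive and 3 in exhausted, and 0 in control and in aged, which allows shares of up to 0.0421% and 0.0445%. The cluster took 97.83% of its cells from aged-injury, so it may be that library as much as its group. Stromal clusters without a class name held 14.2%, 30.1%, 21.8%, 21.5% and 25.3% of stromal cells. The naming thresholds were set after the clusters had been seen. They kept out a deep cluster led by Acta2, Tagln, Hmga2 and Cd248, which held 0.0561%, 2.00%, 0.416%, 0.0148% and 4.36%, and a shallow cluster with a median of 3013 UMIs per cell, which held 9.20%, 19.4%, 16.1%, 14.3% and 18.1%. A further unnamed cluster led by Dnah12 held 3.60%, 2.83%, 2.46%, 5.78% and 1.31%. The last of them, led by Fat3, held 1.36%, 5.90%, 2.84%, 1.45% and 1.59%. Its best-scoring class was osteoblast, with 13 markers detected. It stayed unnamed because none of these was among its 10 leading genes, whereas Fat3, a preosteoblast marker, was. Its 97, 219, 82, 98 and 290 cells are left out of the osteoblast-lineage shares above. In every library but aged-injury they outnumber the osteoblast-like cells, so the order of the libraries for that class depends on this naming.

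**Figure D1:**
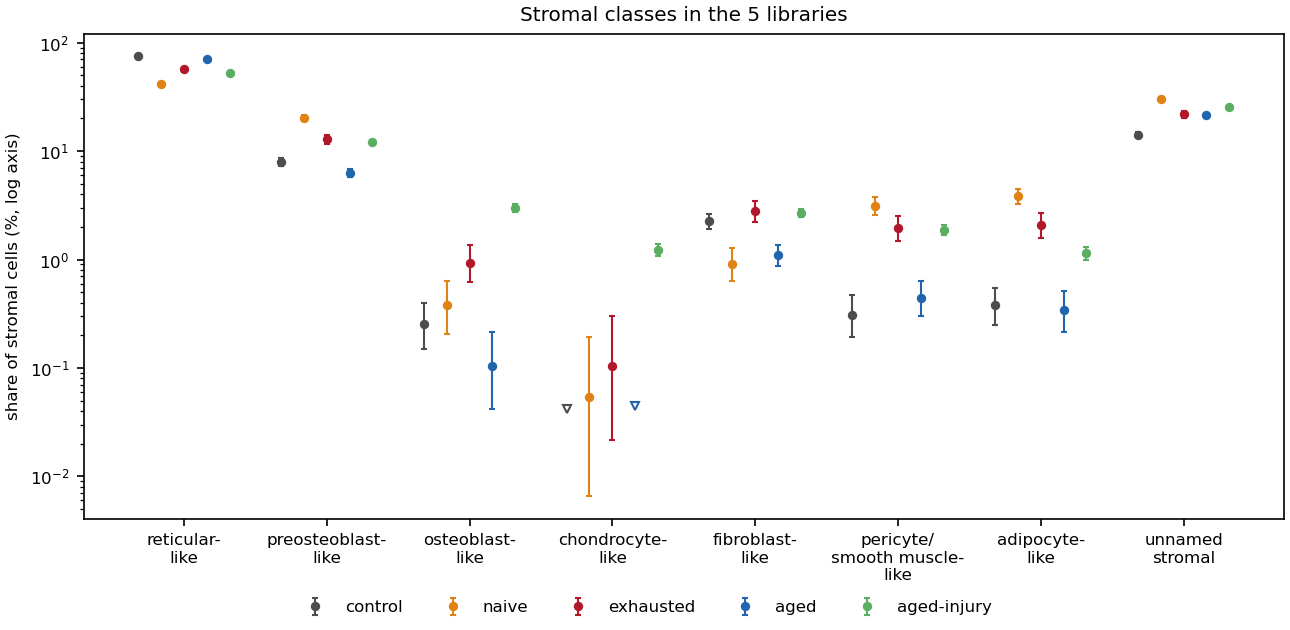
Share of stromal cells (%, log axis) in each stromal class for the 5 libraries; points are single libraries, bars are exact 95% intervals and hollow triangles mark the upper limit where 0 cells were found. Reticular-like cells stand at 74.6% in control and 41.4% in naive, and chondrocyte-like cells at 1.23% in aged-injury.

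Among the 14 genes fixed in advance, several niche genes were lower in each ablated library than in both uninjured ones. Lepr, the receptor that defines the lineage, stood at 4365 CPM in control and 4180 in aged, against 1798 in naive, 2294 in exhausted and 1701 in aged-injury. Cxcl12, the chemokine that retains blood stem cells, stood at 33865 and 35226 CPM in control and aged, and at 18821, 28263 and 21065 in naive, exhausted and aged-injury. Kitl, the stem cell factor gene, stood at 2325 and 2477 CPM in control and aged, and at 1743, 1899 and 1585 in naive, exhausted and aged-injury. The reticular transcription factor genes Foxc1 and Ebf3 were also lower in the ablated libraries: Foxc1 stood at 607, 346, 469, 594 and 369 CPM and Ebf3 at 1165, 871, 1057, 1181 and 853 CPM in control, naive, exhausted, aged and aged-injury. Adipoq, the adiponectin gene, lay between 2639 and 3890 CPM, and Runx2, which starts bone differentiation, between 570 and 643 CPM. Later bone genes spread more widely. Sp7, which acts after Runx2, stood at 35.5, 76.9, 55.0, 27.8 and 64.7 CPM. Alpl, the alkaline phosphatase gene needed for mineralisation, stood at 298, 729, 501, 182 and 541 CPM. Col1a1, the main collagen gene of bone, stood at 2795, 9409, 7693, 1934 and 20051 CPM, and Bglap, the osteocalcin gene of mature osteoblasts, at 119, 146, 105, 33.6 and 553 CPM. Among cell-cycle genes, the arrest gene Cdkn1a stood at 358, 328, 228, 471 and 272 CPM, Cdkn2a at 1.26, 7.19, 2.47, 0.605 and 11.7 CPM, and the division marker Mki67 at 6.20, 12.7, 12.3, 2.74 and 27.7 CPM.

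**Figure D2:**
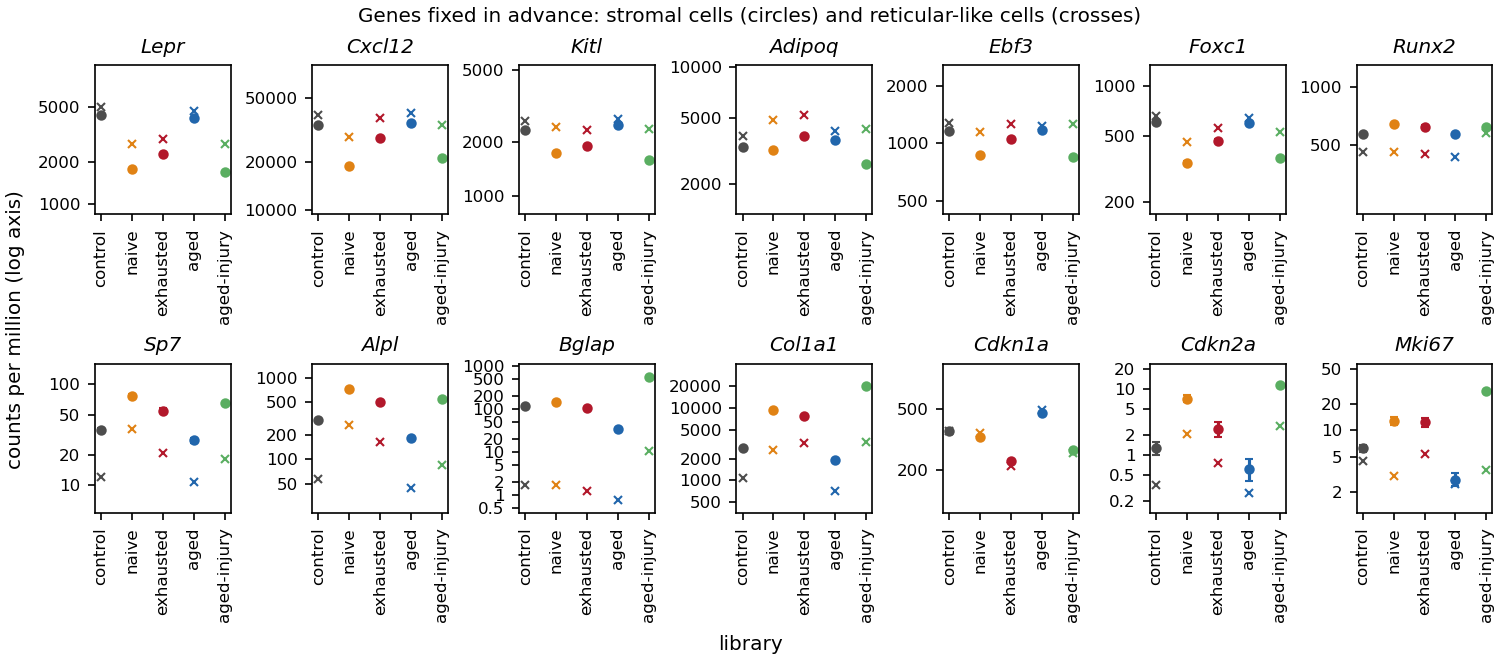
Expression (CPM, log axes) of the 14 genes fixed in advance in each of the 5 libraries; circles are sums over stromal cells with 95% Poisson intervals and crosses are sums over reticular-like cells alone. Lepr stands at 4365 CPM in control and 1798 in naive, and Col1a1 at 2795 and 9409.

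Within reticular-like cells alone, Lepr and Cxcl12, both among the markers that named the class, were closer between the ablated and the uninjured libraries. Lepr stood at 4992, 2694, 2940, 4688 and 2709 CPM and Cxcl12 at 39268, 28664, 37650, 40310 and 33996 CPM in control, naive, exhausted, aged and aged-injury. Col1a1 stood at 1090, 2655, 3248, 720 and 3332 CPM, and Alpl at 57.8, 259, 161, 44.0 and 83.8 CPM. The class was not made of the same clusters in each library. A cluster led by Cbln1 and Grem1 held 25.6%, 40.4%, 56.5%, 23.2% and 40.4% of it. A cluster with the chemokine genes Ccl2, Ccl7 and Cxcl1 among its leading genes held 40.3%, 3.65%, 4.29%, 43.3% and 25.2%. A cluster with the interferon-inducible genes Cxcl9, Iigp1 and Gbp2, together with Kit and Cxcl5, among its leading genes held 0.225%, 8.404%, 3.502%, 0.401% and 26.1%, and 91.99% of its cells came from aged-injury. The remaining reticular-like cells lay in a shallow cluster led by Igfbp5, with 23.5%, 19.9%, 23.4%, 21.9% and 1.24%, and in another led by Kcnq3, with 10.3%, 27.7%, 12.3%, 11.3% and 7.202%.

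Young marrow 2 weeks after ablation was compared with uninjured young marrow to ask how the stromal lineage differs while bone and marrow regrow. The naive stroma held more RNA of fat, bone, matrix and cell division, and less RNA of niche factors, inflammatory factors and early stress genes. The fat and bone genes also stood higher within reticular-like cells alone, with smaller list medians. The reticular identity list had a lower median over all stromal cells but not within reticular-like cells. Nearly all its genes are markers that named this class, so a median near 0 within it was partly built in. Its members fixed in advance as single genes, Lepr, Cxcl12, Kitl, Ebf3 and Foxc1, were each lower in naive within the class too. Across all 10772 genes measured, the median log2 ratio was 0.15, and each gene list was therefore read against random lists of like expression rather than against 0. Scaling by TMM would have lowered every ratio of this comparison by 0.17, raised every ratio of aged-injury against naive by 0.18 and raised those of exhausted against naive by 0.10. No list named here as outside its random range changed sign under it.

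Fat genes stood furthest above control. The adipocyte lineage list had a median log2 ratio of 1.92 (95% interval 0.59 to 3.41), with 14 of 20 members at least 2-fold higher and 6 in between. Fabp4, which carries fatty acids in fat cells, stood at 1167 against 110 CPM, whereas Lpl, the lipoprotein lipase gene already high in reticular cells, had a log2 ratio of -0.22. Fat genes were also among the single genes furthest above control: Pck1, a gene of glycerol synthesis, was 89.4-fold higher (55.5 to 154), the droplet genes Cidec and Plin1 were 31.6-fold (24.995 to 40.4) and 16.4-fold (14.4 to 18.8) higher, and Gpd1 and Thrsp were 29.3-fold and 31.7-fold higher. Fabp5 and Cav1 were 18.3-fold and 18.7-fold higher but are not particular to the stroma. In the non-stromal cells of naive they stood at 123 and 95.4 CPM, against 137 and 42.1 CPM in its stroma. The share of endothelial-like cells was also higher in naive, and whether RNA of other cells or remaining doublets enter the ratios of Fabp5 and Cav1 was not tested. Plin1, Cidec, Gpd1 and Thrsp also lead the adipocyte-like cluster, so they and its share are 1 observation. In reticular-like cells the list median was 0.39. Bone genes came next. The osteoblast differentiation list had a median of 0.83 (0.30 to 1.25), with 8 of 22 members at least 2-fold higher and 1 lower, and a median of 0.59 in reticular-like cells. Col1a1 and Col1a2, the collagen I chains, had log2 ratios of 1.75 and 0.94, and Sparc, a collagen-binding protein of bone, had 0.75, whereas Ibsp, the bone sialoprotein gene, was lower at -0.83. The matrix list had a median of 0.86 (0.48 to 1.23), with 12 of 25 members at least 2-fold higher and none as much lower, and 0.58 in reticular-like cells. In it, the collagen VI chain Col6a2 stood at 1784 against 884 CPM. Chondrogenic genes had a median of 1.07 (-0.13 to 11.43), with 4 of 8 members at least 2-fold higher. Col2a1, the cartilage collagen, stood at 108 against 35.2 CPM. Col10a1, made by hypertrophic cartilage cells, had 0 counts in control and was at least 2765-fold higher in naive, a library with 2 chondrocyte-like cells. The cartilage genes Acan and Chad were 65.8-fold (45.8 to 98.0) and 22.6-fold higher. Signalling lists differed less: TGF-beta and BMP targets had a median of 0.41 (-0.29 to 0.90) and the Notch pathway 0.40 (-1.58 to 1.01), although the Notch target Hes1 stood at 163 against 485 CPM.

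Division genes were higher and niche, inflammatory and early response genes lower. The proliferation list had a median of 1.04 (0.24 to 1.83), with 8 of 15 members at least 2-fold higher. Top2a, which untangles DNA in dividing cells, stood at 14.7 against 7.39 CPM, while Pcna had a log2 ratio of -0.51. The median was 0.12 in reticular-like cells. Niche factors had a median of -0.43 (-0.68 to 0.31), with 12 of 14 members within 2-fold: Cxcl12 and Vcam1, an adhesion molecule for blood cells, had log2 ratios of -0.85 and -0.44, whereas Spp1, the osteopontin gene, was higher at 0.90. The reticular identity list had a median of -0.26 (-0.66 to -0.03), and of 0.07 in reticular-like cells alone. Inflammatory genes had a median of -0.85 (-1.16 to -0.42), with 6 of 16 members at least 2-fold lower and 2 higher, and -0.37 in reticular-like cells. The chemokine gene Cxcl14 stood at 1651 against 3384 CPM, and Nfkbia, the brake on NF-kappa-B, at 344 against 668 CPM. Immediate early and heat shock genes had a median of -0.80 (-1.16 to -0.52), and -0.59 in reticular-like cells. Fos, an early transcription factor, stood at 3494 against 8612 CPM. Antigen presentation genes had a median of -0.29 (-0.43 to -0.14), angiogenic factors -0.16 (-0.89 to 0.02), acute phase and complement genes -0.29 (-0.76 to 0.28), and unfolded protein genes -0.39 (-0.66 to 0.04). In the last of these the chaperone gene Hspa5 stood at 1454 against 2387 CPM. Among single genes Shisa3 had the widest gap below control, at 12.6-fold lower (9.65 to 16.6), and Steap3 was 6.09-fold lower (5.61 to 6.62). Gpr50, Ces1g, Dio2, C1qtnf2, Apod, Ifitm1, Adamdec1 and Slco1a4 were lower by 8.12-fold to 4.21-fold. The naive and control libraries held like shares of blood cells, 23.6% and 21.6%, and the myeloid and erythroid lists had medians of -1.33 and -0.80 in the stromal sums. Early response genes also respond to tissue digestion, whose timing the labels do not give.

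A repeat ablation was compared with uninjured marrow and with the first ablation to ask whether an earlier injury alters how the lineage stands 2 weeks after the later one. The exhausted stroma lay between control and naive for most gene groups that had set naive apart. Its fat and matrix list medians were above control and below naive, its bone median was below naive and above control with an interval that included 0, its niche and reticular list medians were near 0 against control although Lepr, Cxcl12 and Kitl were lower, and its inflammatory and early response medians were above naive and below control, in both cases with an interval against control that included 0. Of the lists, fat genes had the lowest median against naive. These readings come from a library in which blood cells were 50.8% of the filtered cells, more than in any other library. With all filtered cells summed, the osteoblast, chondrogenic and matrix medians against control and the niche and reticular medians against naive had the opposite sign.

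Against control, the adipocyte lineage list had a median log2 ratio of 0.84 (0.30 to 1.88), with 8 of 19 members at least 2-fold higher, and 0.20 in reticular-like cells. The osteoblast list had a median of 0.63 (-0.09 to 0.76), with 2 of 22 members at least 2-fold higher, and 0.13 in reticular-like cells. Col1a1 and Sparc had log2 ratios of 1.46 and 0.67. The matrix list had a median of 0.59 (0.10 to 0.88), with 6 of 25 members at least 2-fold higher, and 0.44 in reticular-like cells. Matrix genes also led the single genes above control: Fmod, which organises collagen fibres, was 10.1-fold higher (9.02 to 11.4) and Fn1, the fibronectin gene, 5.06-fold higher (4.83 to 5.30). Eln, Col8a2 and Npnt were 5.61-fold, 5.45-fold and 4.14-fold higher. The Wnt-binding factor gene Sfrp2 was 5.72-fold higher, the fat cell gene Cfd 8.57-fold, Ecrg4 7.09-fold and Cdo1 4.93-fold. Rgs5, a gene of vessel-wall cells, was 4.32-fold higher over all stromal cells but lower in reticular-like cells, with a log2 ratio of -0.61. Chondrogenic genes had a median of 0.78 (0.04 to 3.93), with Comp, a cartilage and tendon matrix gene, at 87.2 against 25.9 CPM. Proliferation genes had a median of 0.63 (-0.11 to 0.99), and TGF-beta and BMP targets 0.35 (-0.22 to 0.63). Niche factors and reticular identity had medians of 0.02 and -0.05, inside their random ranges. Inflammatory genes had a median of -0.34 (-0.68 to 0.56), early response genes -0.17 (-0.48 to 0.05), acute phase genes -0.36 (-0.65 to 0.36), interferon response -0.06 (-0.22 to 0.10), antigen presentation -0.12 (-0.43 to 0.74), skeletal progenitor genes -0.10 (-0.56 to 0.42) and angiogenic factors -0.19 (-0.40 to 0.13). The heat shock genes Hspa1b and Hspa1a were 3.89-fold and 3.06-fold lower, and Shisa3 had the widest gap below control, at 7.87-fold (6.14 to 10.3). C1qtnf2, Ces1g, Gpr50, Ifitm1, Apod, Hsd11b1 and Adm were 4.65-fold to 3.10-fold lower.

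Against naive, fat genes were lower after the repeat ablation. Their list had a median log2 ratio of -0.89 (-1.53 to -0.25), with 8 of 20 members at least 2-fold lower, and -0.20 in reticular-like cells. Fabp4 stood at 444 against 1167 CPM, and Pck1, Plin1, Fabp5, Cd36 and Gpd1 were 9.66-fold (7.38 to 12.9), 4.44-fold, 4.22-fold, 3.09-fold and 3.01-fold lower. Of these, Fabp5 and Cd36 stood at 123 and 198 CPM in the non-stromal cells of naive, against 137 and 78.0 CPM in its stroma. Whether RNA of those cells enters the ratios of Fabp5 and Cd36 was not tested. Col10a1 was 231-fold lower (135 to 435) and the cartilage gene Acan 4.31-fold lower, while the chondrogenic list median was -0.34 (-7.85 to 0.83). Bone genes had a median of -0.29 (-0.48 to -0.08) and matrix genes -0.33 (-0.45 to -0.16), with no matrix member 2-fold apart. Spp1 was lower, with a log2 ratio of -0.99. Contractile genes had a median of -0.35 (-1.47 to -0.01), with Acta2, the smooth muscle actin gene, 4.08-fold lower, and Col15a1 and Meg3 were 3.76-fold and 3.83-fold lower. On the other side, reticular identity had a median of 0.24 (0.13 to 0.35) and niche factors 0.23 (0.02 to 0.59), with Cxcl12 at a log2 ratio of 0.59 and no member of either list 2-fold apart. Inflammatory genes had a median of 0.46 (0.15 to 0.97) and early response genes 0.55 (0.27 to 0.77), with Jun at 3848 against 2096 CPM, Nfkbia at 588 against 344 CPM and the neutrophil-attracting chemokine gene Cxcl1 2.63-fold higher (2.49 to 2.77). Unfolded protein genes had a median of 0.32 (0.13 to 0.67), antigen presentation 0.10 (-0.06 to 1.15) and Wnt antagonists 0.24 (-1.88 to 0.70). Steap3, a metal reductase gene, led the genes above naive at 3.85-fold (3.51 to 4.23). Tmem37, Cbln2, H19, Adamdec1, Col6a5 and Ptchd1 were 3.42-fold to 2.27-fold higher. Dio2 and Itgbl1 were 3.76-fold and 2.99-fold higher over all stromal cells but lower in reticular-like cells, with log2 ratios of -1.07 and -0.97. The myeloid and erythroid lists had medians of 1.22 and 0.67 in these stromal sums, beside blood cell shares of 50.8% and 23.6%.

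Uninjured marrow of 18 months was compared with uninjured marrow of 15 weeks to ask how the lineage differs with age. The stroma of both ages was alike in its reticular identity and fat genes, whose list medians were 0.00 and -0.07, inside their random ranges. Bone genes were lower in the aged library and inflammatory genes higher, and the latter held within reticular-like cells. The osteoblast list had a median log2 ratio of -0.51 (-0.59 to -0.07), with 2 of 21 members at least 2-fold lower, and -0.13 in reticular-like cells. The osteocalcin genes Bglap and Bglap2 were 3.54-fold (3.36 to 3.74) and 3.06-fold lower, and Col1a1 and Sparc had log2 ratios of -0.53 and -0.51. Bglap and Bglap2 lead the osteoblast-like cluster, which held 18 cells in control and 7 in aged, or 66 and 39 without the transgene features. The interval counts UMIs and does not cover the sampling of so few cells. Inflammatory genes had a median of 0.52 (0.37 to 1.32), with 5 of 16 members at least 2-fold higher and 1 lower, and 0.62 in reticular-like cells. Ccl2, which draws monocytes, stood at 370 against 148 CPM. Glycolysis and hypoxia genes had a median of 0.33 (0.07 to 0.50), and 0.35 in reticular-like cells, with the vessel growth factor gene Vegfa at 927 against 617 CPM. Interferon response genes were lower, with a median of -0.27 (-0.46 to -0.13), and -0.24 in reticular-like cells, and the interferon-induced chemokine gene Cxcl9 stood at 170 against 288 CPM. Smaller medians outside the random range were those of niche factors at -0.18 (-0.54 to 0.06), matrix genes at -0.12 (-0.29 to -0.02), contractile genes at -0.23 (-0.55 to -0.08), unfolded protein genes at -0.17 (-0.29 to 0.11), early response genes at 0.14 (-0.09 to 0.21) and chondrogenic genes at 0.31 (-0.62 to 1.12). Wnt antagonists had a median of -0.41 over 5 members, with Wif1 at 115 against 205 CPM. Single genes above control were led by Ngfr, the low-affinity nerve growth factor receptor gene, at 14.6-fold (11.95 to 18.0). They included the integrin gene Itga6 at 9.06-fold, Lgr5 at 5.82-fold (5.31 to 6.40) and the B cell chemokine gene Cxcl13 at 3.47-fold. Snhg11, Ces1d, Slco2a1, Vtn, Greb1 and Tenm2 were 8.88-fold to 2.73-fold higher. Cbln2, the imprinted transcript H19, Car3, Col14a1, Palmd, Rgs4 and Ifitm1 were 4.50-fold to 2.74-fold lower. The reporter transcript EGFP was at least 619-fold lower than in control, but the aged library does not list it and its reference may have lacked it. Blood cells were 9.65% of the aged library and 21.6% of control, and the myeloid and erythroid lists had medians of -1.90 and -0.63 in the stromal sums.

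Aged marrow 1 week after ablation was compared with uninjured aged marrow to ask how the old lineage differs after the same injury. The aged-injury stroma stood far above the aged stroma in bone, cartilage, matrix and division genes, and below it in reticular, niche and inflammatory genes, the directions already described for young marrow. Interferon and ribosomal protein genes were also higher, whereas in young marrow their medians of 0.13 and 0.12 lay inside the random range and changed sign under TMM. Many of the cartilage genes also mark the chondrocyte-like cluster, so the list and the class share are not independent observations.

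The osteoblast differentiation list had a median log2 ratio of 1.75 (1.22 to 2.85), with 17 of 22 members at least 2-fold higher and none as much lower, and 0.68 in reticular-like cells. Col1a1, Col1a2 and Sparc had log2 ratios of 3.37, 2.07 and 1.74, whereas Ibsp was lower at -0.75. Spp1 stood at 3258 against 565 CPM. Matrix genes had a median of 1.06 (0.33 to 1.54), with 13 of 25 members at least 2-fold higher, and 0.76 in reticular-like cells, with Col3a1, the collagen of early repair tissue, at 2082 against 244 CPM. Chondrogenic genes had a median of 6.95 (-0.01 to 9.68), with 11 of 14 members at least 2-fold higher, and 0.40 in reticular-like cells. Col2a1 stood at 1580 against 44.7 CPM. Col10a1 had 1 count in aged and was 17484-fold higher (3138 to 690575), Col9a1 1814-fold (708 to 6657), Acan 746-fold (362 to 1855), Cnmd 448-fold (175 to 1644), Hapln1 361.0-fold (207 to 699) and Col9a3 206-fold (127 to 361). Snorc had 0 counts in aged and was at least 820.0-fold higher. Outside cartilage, the collagen-linked gene Cthrc1 and the tenascin gene Tnn were 165-fold (106 to 275) and 148-fold (88.2 to 271) higher. The EGFP transcript was at least 2820-fold higher, under the same limit. Proliferation genes had a median of 2.79 (1.92 to 3.89), with 17 of 20 members at least 2-fold higher. The median was 0.29 in reticular-like cells and -0.23 over all filtered cells, and Top2a stood at 43.2 against 2.60 CPM. The adipocyte lineage list had a median of 0.40 (-0.04 to 2.88), with 4 of 16 members at least 2-fold higher and 1 lower. Skeletal progenitor genes had a median of 0.41 (-0.35 to 1.24), p53 and arrest genes 0.44 (0.19 to 0.91) and Wnt antagonists 0.67 (-0.69 to 3.76). In the p53 list Cdkn1a was lower, with a log2 ratio of -0.79, and Ccng1 higher at 0.91.

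Interferon response genes had a median of 0.82 (0.50 to 1.14), with 7 of 21 members at least 2-fold higher and 1 lower, and 1.03 in reticular-like cells. Its members Cxcl9, Iigp1 and Gbp2 also lead a reticular-like cluster that held 26.1% of the class in aged-injury and 0.401% in aged. The list and the share of that cluster are therefore not independent observations, here and where aged-injury is set against naive. Cxcl9 stood at 509 against 170 CPM and the interferon-induced GTPase gene Iigp1 at 445 against 261 CPM, while Irf1 and Ifitm3 were lower, with log2 ratios of -1.02 and -0.66. Ribosomal protein genes had a median of 0.65 (0.51 to 0.86), and 0.36 in reticular-like cells, and oxidative phosphorylation genes 0.38 (0.10 to 0.59). Reticular identity had a median of -0.47 (-0.74 to -0.17), and -0.01 in reticular-like cells, a class that nearly all of these genes served to name. Niche factors had a median of -0.38 (-0.91 to 0.26), with Lepr and Cxcl12 at log2 ratios of -1.30 and -0.74. Inflammatory genes had a median of -0.54 (-0.96 to 0.18), early response genes -0.65 (-0.76 to -0.04), acute phase genes -0.40 (-0.82 to 0.02) and angiogenic factors -0.36 (-0.74 to 0.26). Cxcl14 and Nfkbia had log2 ratios of -1.19 and -1.02, and Il34, a growth factor gene for macrophages, was 3.76-fold lower (3.64 to 3.88). Tenm2, which codes for a cell adhesion protein, and Ngfr, both higher in aged than in control, were 6.28-fold (5.96 to 6.61) and 4.07-fold lower in aged-injury than in aged. The glutamate receptor genes Grik3 and Grm7 were 5.87-fold and 4.14-fold lower, and Gpr50, Ces1g, Grip1 and Ralyl 5.05-fold to 3.81-fold lower. Blood cells were 1.86% of this library, and the myeloid list had a median of -2.16 over 5 members.

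The aged-injury library was also set against the naive library, the pair of libraries with a single ablation, which differ in age and in the weeks since surgery, so neither could be told apart from the other. Fat genes were lower in aged-injury and cartilage, bone, inflammatory and interferon genes higher, while the direction of division genes depended on the cells summed. The adipocyte lineage list had a median log2 ratio of -1.54 (-2.21 to -0.56), with 13 of 20 members at least 2-fold lower, but -0.04 in reticular-like cells. Cidec, Gpd1, Pck1 and Cfd were 16.9-fold (15.1 to 18.8), 15.8-fold, 14.7-fold and 10.4-fold lower in aged-injury. Thrsp, Plin1 and Acsl1 were 12.8-fold, 4.90-fold and 4.61-fold lower over all stromal cells but had log2 ratios of 0.12, 0.95 and 0.17 in reticular-like cells. The transcription factor gene Zbtb16, with Frmd5 and Nlgn1, was also among the widest gaps, at 4.28-fold, 5.44-fold and 4.27-fold lower. Chondrogenic genes had a median of 3.44 (0.88 to 5.40), with 11 of 14 members at least 2-fold higher, but -0.42 in reticular-like cells. Col2a1 was 14.6-fold higher (14.1 to 15.1), Cnmd, with 2 counts in naive, 593-fold (164 to 4895), and Col9a1, Hapln1, Matn3, Col9a3 and Snorc 64.9-fold to 20.6-fold. Osteoblast genes had a median of 0.70 (0.00 to 1.09), with 7 of 22 members at least 2-fold higher, and 0.32 in reticular-like cells. Proliferation genes had a median of 0.99 (0.73 to 1.27), 0.16 in reticular-like cells, -0.49 over named stromal clusters only and -1.46 over all filtered cells. Inflammatory genes had a median of 0.87 (0.44 to 1.99), and 1.01 in reticular-like cells, with the chemokine gene Cxcl5 8.44-fold higher (7.12 to 10.1). Interferon response genes had a median of 0.45 (0.25 to 0.70), and 0.47 in reticular-like cells, with Cxcl9 at 509 against 114 CPM. Antigen presentation had a median of 0.23 (0.07 to 0.72), early response genes 0.42 (0.11 to 0.64), ribosomal protein genes 0.45 (0.28 to 0.63), glycolysis genes 0.40 (-0.07 to 0.74), unfolded protein genes 0.29 (0.04 to 0.73), p53 and arrest genes 0.31 (-0.02 to 0.67), Wnt antagonists 0.33 (-1.10 to 1.73) and niche factors -0.33 (-0.71 to 0.18). The clock gene Nr1d1 was 12.4-fold higher (11.002 to 14.0). Pcolce2, a collagen-processing gene, was 10.8-fold higher over all stromal cells but lower in reticular-like cells, with a log2 ratio of -0.46. The myeloid list had a median of -2.92 over 5 members.

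**Figure D3:**
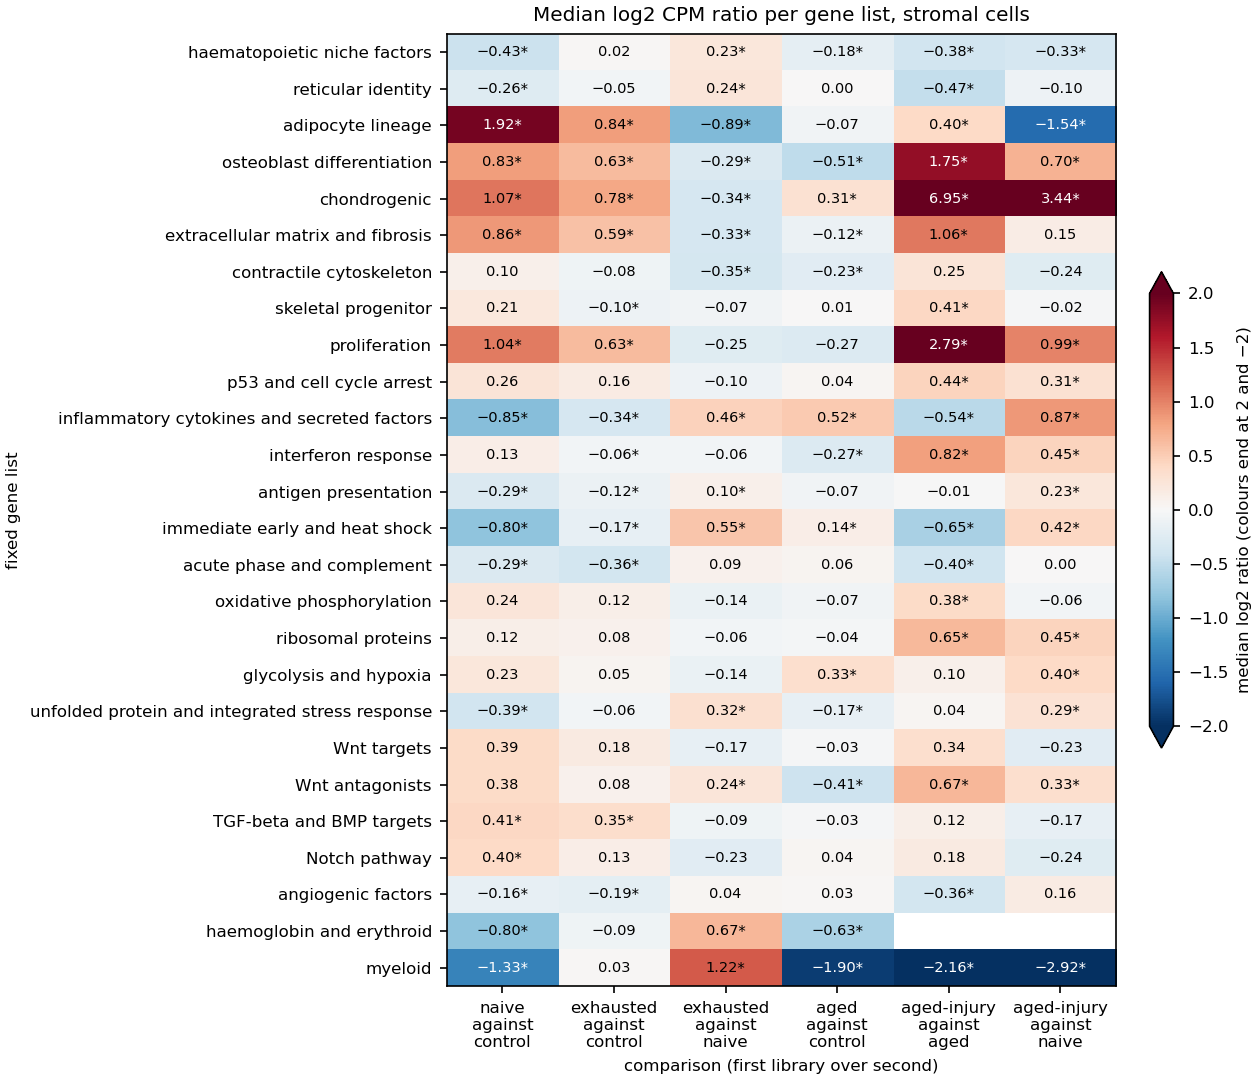
Median log2 CPM ratio of 26 fixed gene lists (vertical axis) in the 6 comparisons (horizontal axis), over stromal cells; colour gives the median and ends at 2 and -2, an asterisk marks a median outside the central 95% of random lists of like expression, and blank cells had under 5 members. The adipocyte lineage stands at 1.92 in naive against control and at -0.89 in exhausted against naive, and the proliferation list at 2.79 in aged-injury against aged.

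Both ages were then compared in how far their ablated stroma stood from their uninjured stroma, gene by gene within each list. Over all stromal cells the aged pair stood further apart in division, bone, interferon and ribosomal protein genes, and less far apart in fat genes. The median of the aged minus the young log2 ratio was 2.04 (0.86 to 2.30) over 15 proliferation genes, 1.04 (0.28 to 1.62) over 22 osteoblast genes, 0.80 (0.61 to 1.01) over 20 interferon genes and 0.47 (0.33 to 0.70) over 24 ribosomal protein genes. Antigen presentation had 0.28 (0.12 to 1.33) and unfolded protein genes 0.57 (0.01 to 0.91), while the adipocyte lineage had -0.48 (-1.51 to -0.10) over 16 genes. Within reticular-like cells alone the division and bone gaps were small: the proliferation medians, each over 6 genes, were 0.12 in the young and 0.29 in the aged pair, and the osteoblast medians 0.59 and 0.68. With all filtered cells summed, the proliferation median of the aged pair was -0.23, with the opposite sign. Matrix genes, at 0.22 (-0.03 to 0.89), and the niche, reticular and inflammatory lists had intervals that included 0. Since the weeks after surgery differ between the ages, these gaps cannot be assigned to age. Across 8057 genes the log2 ratios of the young and the aged pair had a Pearson r of 0.495 and a Spearman rho of 0.393. In contrast, the ratios of repeat against first ablation and of aged against control had an r of -0.085 and a rho of -0.103 across 8117 genes. These were the 2 relations computed; neither pair of ratios shares a library, and genes are not independent replicates. The latter r was -0.669 when all filtered cells were summed.

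Dividing cells were counted after each cell had been thinned to 1500 UMIs. Molecules of at least 2 proliferation genes were found in 5.21% (4.70 to 5.76) of stromal cells in control, 3.70% (3.10 to 4.37) in naive, 5.67% (4.85 to 6.58) in exhausted, 3.63% (3.19 to 4.11) in aged and 6.61% (6.24 to 6.999) in aged-injury. Mature neutrophil-like cells, which do not divide, gave 6.52%, 10.3%, 7.85%, 9.68% and, from 11 cells, 18.2% at the same depth. The rule therefore also takes in cells that do not divide, and no difference in cycling was read from the stromal shares. Those were lower than the neutrophil-like shares in every library, so neutrophil-like cells do not measure the stromal background. With at least 3 genes, the shares were 0.617% (0.447 to 0.830), 1.15% (0.825 to 1.55), 0.775% (0.486 to 1.17), 0.137% (0.0625 to 0.259) and 2.28% (2.06 to 2.52), which put naive above control, the opposite order. The neutrophil-like cells then gave 2 of 322, 0 of 174, 5 of 599, 1 of 93 and 0 of 11 cells. Under this rule aged-injury stood above aged, but 11 neutrophil-like cells give it no usable reference of its own.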

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

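All tests of this part were chosen after the result had been seen. A signal appeared in a feature that no comparison was built on: EGFP, a fluorescent protein that the labelled genotype does not name, was counted in 4 of the libraries. In stromal cells it stood at 50.6 CPM in naive and 171 CPM in aged-injury, above the 37.5 CPM of control, and at 32.9 CPM in exhausted. The aged library had 0 EGFP UMIs in all its deposited cells, against 2495 in control, 1847 in naive, 867 in exhausted and 35737 in aged-injury. The transcript was concentrated in mature osteoblast-like cells, where it stood at 5002, 4490, 2050 and 2351 CPM in control, naive, exhausted and aged-injury, and it is among the leading genes of that cluster. An EGFP UMI was found in 16 of 18, 13 of 14, 15 of 27 and 390 of 543 of those cells, or 88.9% (65.3 to 98.6), 92.9% (66.1 to 99.8), 55.6% (35.3 to 74.5) and 71.8% (67.8 to 75.6), in 0 of 7 in aged, and in 13.2%, 5.61%, 3.49% and 14.2% of preosteoblast-like cells. In blood cells, taken as background, the shares were 0.957%, 1.54%, 0.314% and 3.31%, at median depths of 8866, 8537, 8026 and 8956.5 UMIs. Over all libraries the osteoblast-like cluster was deeper, at a median of 22489 UMIs, as were the preosteoblast-like clusters at 11668 and 15088, so the shares are not at matched depth. Because EGFP took part in building these clusters, the classes were also taken from clusters built without the transgene features. There the osteoblast-like cells with an EGFP UMI were 38 of 66, 40 of 69, 23 of 46, 0 of 39 and 527 of 783 in control, naive, exhausted, aged and aged-injury, with intervals of 44.8% to 69.7%, 45.5% to 69.8%, 34.9% to 65.1%, 0% to 9.03% and 63.9% to 70.6%.

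For the missing EGFP of the aged library, the tables argue against a lack of cells or depth. The lowest share of preosteoblast-like cells with EGFP elsewhere was 3.49% (1.87 to 5.89) in exhausted, while 0 of 424 such cells in aged allow up to 0.708%. Scaled for depth, EGFP in these cells stood at 19.5 CPM in exhausted, while 0 counts in aged allow up to 0.729 CPM. In clusters built without the transgene features the preosteoblast-like share of exhausted was lower, at 1.47% (0.594 to 3.01). The exact interval for 0 of 514 such cells in aged reaches 0.715%, so the intervals of the preosteoblast-like shares overlap there. The osteoblast-like cells therefore carry more of this argument. They also argue against free RNA as the origin of the counts in the other libraries, since in the clusters built without the transgene features EGFP stood at 2313 CPM in osteoblast-like cells of control and at 1.07 CPM in its blood cells, a ratio of 2160. A different genotype and a reference without EGFP for that library both stay open and cannot be told apart. The aged library held 4274 UMIs of tdTomato, 67 of the feature tdTomato-RC listed beside it and 7 of Cre. Its reference therefore held several of the transgene sequences counted in the other libraries, but these counts do not show whether EGFP was among them. An osteoblast reporter allele carried by the mice of the other libraries is a candidate explanation for the class pattern, which the sources used here neither state nor exclude. Age alone is argued against, since the other library of 18 months had the most EGFP UMIs.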

How the results depend on the processing

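Alternatives chosen after the data were seen are those with named stromal clusters only, without transgene features and without the cells of highest doublet score, and the shares of stromal cells given beside those of filtered cells. TMM scaling, a minimum of 50 CPM and removal of the 5% of cells with the highest doublet score moved none of the 14 main values computed under them, the reticular and osteoblast list medians and the correlations, beyond their intervals; class shares and cycling cells were not recomputed under them. Under these settings, 33, 2 and 11 values of single genes or lists moved, and no named gene and no list outside its random range changed sign. No paired analysis was possible because each group had 1 library and no test was run. Every alternative set in advance was run. Where a value moved or changed sign, the cause was not tested unless stated. Shares here are of filtered cells, in the order control, naive, exhausted, aged and aged-injury.

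The stricter cell filter gave a reticular-like share of 66.2%, 36.8%, 29.4%, 76.4% and 51.9% and an osteoblast-lineage-like share of 3.91%, 10.8%, 4.68%, 3.86% and 12.2%. Its correlation of injury responses in young and aged was 0.561, that of repeat ablation and ageing differences -0.062, and its cycling stromal cells were 4.71% in naive and 5.90% in aged-injury. Keeping doublets gave a reticular-like share of 60.9%, 33.3%, 28.1%, 68.8% and 52.7%, and an osteoblast-lineage-like share of 7.33% in control, 17.4% in naive, 6.72% in aged and 16.6% in aged-injury. Only 2 doublets had been called in aged and 0 in aged-injury, so the added cells do not account for the shifts there. The clusters were built anew under this setting, and the counting intervals do not cover where cluster borders fall. At Leiden resolution 0.5 the reticular-like share was 55.1%, 24.4%, 24.9%, 59.3% and 39.9% and the osteoblast-lineage-like share of aged-injury 13.7%. At resolution 2.0 the reticular-like share was 62.1% in control, 27.8% in naive and 71.2% in aged, and the osteoblast-lineage-like share 5.36% in control, 5.04% in exhausted, 4.67% in aged and 10.2% in aged-injury. Without transgene features the reticular-like share was 53.1%, 20.9%, 22.97%, 56.6% and 45.6% and the osteoblast-lineage-like share 7.68%, 20.02%, 8.31%, 7.32% and 16.4%. In all of these, reticular-like shares were lower in naive and exhausted than in control, and lower in aged-injury than in aged, and osteoblast-lineage-like shares were higher in naive than in control and in aged-injury than in aged.

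With all filtered cells summed, blood cells entered the sums by construction. The correlations were 0.431 and -0.669. The reticular identity median was -0.95 in exhausted against control, 0.22 in aged against control and, with the opposite sign, 0.42 in aged-injury against naive and -0.51 in exhausted against naive. Osteoblast differentiation changed sign to -0.30 in exhausted against control and had -1.06 in exhausted against naive and 1.19 in aged-injury against naive. In exhausted against control, chondrogenic genes had -0.11 and extracellular matrix and fibrosis -0.23, both with the opposite sign. In exhausted against naive, haematopoietic niche factors at -0.44 and the gene Fabp5 at 0.47 changed sign, as did extracellular matrix and fibrosis at 0.10 in aged against control, proliferation at -0.23 in aged-injury against aged, and proliferation at -1.46 and antigen presentation at -0.17 in aged-injury against naive.

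Reticular-like cells alone leave out the other stromal classes by construction. Nearly all reticular identity genes were also markers that named these cells, so the medians of that list within the class are not an independent reading. The correlations were 0.419 and -0.118, and cycling cells 4.53% in control and 4.42% in aged-injury. Reticular identity changed sign to 0.072 in naive against control and to 0.059 in exhausted against control, and was 0.077 in exhausted against naive and -0.012 in aged-injury against aged, where osteoblast differentiation was 0.68. Rgs5 changed sign to -0.61 in exhausted against control, and Dio2 and Itgbl1 to -1.07 and -0.97 in exhausted against naive. In aged-injury against naive, chondrogenic genes changed sign to -0.42, Pcolce2 to -0.46, Thrsp to 0.12, Plin1 to 0.95 and Acsl1 to 0.17. With named stromal clusters only, the correlations were 0.541 and -0.021, and proliferation in aged-injury against naive changed sign to -0.49.

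Weighting every cell equally gave correlations of 0.534 and -0.143, thinned cells 0.392 and -0.116, and no minimum with 0.5 added 0.341 for the young and aged injury responses. With at least 3 genes, cycling stromal cells were 0.617%, 1.15%, 0.775%, 0.137% and 2.28%, with naive above control, the opposite of the main order, and with no thinning 46.5%, 33.2%, 40.0%, 31.6% and 48.2%, where depth enters the count by construction. Depth limits the low-count genes most: a gene with 0 counts in the stroma of exhausted, the shallowest of the stromal sums, can stand at up to 0.130 CPM.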

Other observations

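The tests of the chondrocyte-like cells and of the clock genes, by class mix and across cell types, were written after the data had been seen. The comparison of the clock genes with other genes was a later addition. The cells outside the stroma, which the sort on tdTomato should largely remove, differed between the libraries as well. Monocyte and macrophage-like cells, led by the complement genes C1qa, C1qb and C1qc, were 1.46% of filtered cells in control, 2.94% in naive, 9.03% in exhausted, 0.318% in aged and 0.0769% in aged-injury. Osteoclast-like cells, the bone-resorbing cells marked by Acp5 and Atp6v0d2, were 0.0326%, 0.210%, 1.15%, 0.0132% and 0.0205%, which is 3, 11, 72, 1 and 4 cells. They had a median of 28870 UMIs, and whether some of them hold more than 1 cell was not tested. Neutrophil-like cells were 7.21%, 5.33%, 15.3%, 2.39% and 0.164%, and B-cell-like cells 4.11%, 6.37%, 9.62%, 1.958% and 0.282%. Endothelial-like cells, which line vessels, were 0.794%, 5.49%, 3.11%, 1.14% and 4.31%, higher in each ablated library than in the uninjured library of its age. How cells entered the sort gate is not known for any library, so these shares do not measure the marrow itself.

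Xist, transcribed from the inactive X chromosome of females, was counted in 79.1%, 79.1%, 77.2%, 75.9% and 88.9% of stromal cells in control, naive, exhausted, aged and aged-injury. The Y-linked gene Ddx3y stood at 2.78, 2.16, 2.65, 2.89 and 0.875 CPM, so no library stood apart as male. The aged-injury library had the lowest Ddx3y value and the highest Xist share. Whether its mix of sexes differed from that of the other libraries was not tested.

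Chondrocyte-like cells were found almost only in aged-injury, 225 cells, or 1.23% of its stroma, with Col10a1, Col9a1 and Acan among their leading genes. The larger cell number of that library does not account for them, since at its share 82.9 such cells would be expected in the aged library and 0 were found. In the same library, tdTomato stood at 51.6 CPM in these cells, between 24.2 CPM in blood cells and 77.9 CPM in reticular-like cells. This does not decide whether unlabelled cartilage cells were carried through the sort. Doublets remain, the cluster was deep at a median of 21646 UMIs, and a doublet with a labelled cell would also hold tdTomato. The residue of growth plate left at dissection, a batch of its own and the shorter time since surgery stay open, since the design ties all of them to this library. Age is shared with the aged library, which held 0 such cells, so it stays open only in combination with the injury. A cartilage stage early after ablation is therefore a hypothesis that these data leave untested.

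Genes of the circadian clock set the aged-injury library apart. Nr1d1, a repressor within the clock, stood at 12.7, 8.26, 7.90, 17.2 and 102 CPM in the stroma of control, naive, exhausted, aged and aged-injury, and Nr1d2 at 18.7, 19.3, 15.5, 21.6 and 73.5 CPM. Arntl, an activator that they repress, stood at 33.5, 37.5, 34.6, 37.3 and 18.4 CPM, and Npas2 at 68.5, 74.6, 64.3, 82.8 and 31.7 CPM. Another mix of stromal classes was argued against, since in reticular-like cells alone the log2 ratio of Nr1d1 in aged-injury against aged was 114.0% of that in the stroma. The clusters within that class differed too, and the one led by Igfbp5 held 1.24% of it in aged-injury and 21.9% in aged. Whether the mix of clusters within the class enters the ratio was not tested. Of 16 clock genes apart in reticular-like cells, 87.5% (61.7 to 98.4) had the same sign in endothelial-like cells. This does not decide whether a cause acted on every cell of the library, such as the time of day at collection or a batch, because other genes shared their sign nearly as often. The share was 69.8% over 9067 other genes apart in reticular-like cells, and 73.7% over genes matched to each clock gene by sign, size of the ratio and endothelial count. Reticular RNA was also present in the endothelial-like cells: the reticular markers stood there at a median of 14.7% of their reticular CPM in aged-injury and 29.6% in aged. With these shares taken off, 12 of the 16 clock genes had the same sign. Arntl had a log2 ratio of -1.02 in the stroma and 0.26 in blood cells. The labels give no time of collection, and an effect of injury in old mice on the clock stays open as untested.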
